A study of Mus musculus with 6 samples.

How the data were processed

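The samples were brown adipose tissue of C57BL/6N mice aged 20 weeks on chow, 3 libraries of wild type (WT) and 3 of ADCY3∆AT, the knockout of the form of adenylyl cyclase 3 that the labels call Adcy3-AT. Per the labels' protocols, tissue was lysed in TRIzol, RNA was taken from it on spin columns, and paired-end libraries of polyadenylated RNA were made with a NEBNext Ultra II kit. Whether the kit or the counting kept the strand is not given in the sources used here, so reads of a gene and of an overlapping or antisense gene cannot be told apart. The labels of each sample call the tissue interscapular, while the design text of the series calls it inguinal. Interscapular was kept in the text because it stands in every sample's own label.

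The authors deposited 1 table of estimated counts per gene, with 6 library columns and 54385 rows. Its values carry 3 decimals, and 38.0% of the values above 0 were whole numbers within a tolerance of 0.0005, so they are estimated counts and not counts of whole reads. The submitters' processing notes name the GRCm38 build, StringTie, Salmon and edgeR, without versions or the role of each. Columns were matched to samples by the number that each sample's description gives. A symbol from the GENCODE M21 annotation of GRCm38 was found for 54131 rows. No symbol was found for the other 254, and 1 of these has an identifier whose form differs from those of Ensembl. No row of totals or unassigned reads was found, and no library column was left out. Pairs of libraries of the same genotype differed by more than counting noise (chi-square per gene from 6.35 to 26.6), so each was counted as 1 replicate. Whether the replicates came from separate mice is not given in the sources used here. The p-values then measure the spread between these libraries, part of which could be technical.

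Estimated counts were rounded to whole numbers. Genes were kept with filterByExpr by genotype (minimum count 10, minimum total count 15), which left 14332. Libraries were scaled by trimmed mean of M-values (TMM), and genotypes were compared with the two-sided quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with all 6 libraries and no covariate. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. CPM are TMM-scaled counts from the cpm function of edgeR, given as mean ± SD with n = 3 per genotype. Log2 fold changes are ADCY3∆AT minus WT, with the standard error (SE) from the F statistic and 95% intervals from its moderated degrees of freedom. Single values were set beside an exact permutation test of log2(CPM + 0.5), two-sided, over the 10 divisions of the libraries into 3 and 3, whose smallest p is 0.1. Library totals ran from 13758492 to 19592156 estimated counts. A count of 0 allows up to 3 counts, a limit for counting error only.

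Fixed before the data were examined were 25 gene lists: brown fat thermogenic genes, cyclic AMP machinery, immediate targets of cyclic AMP, nuclear and mitochondrial genes of oxidative phosphorylation, fatty acid oxidation, lipogenesis, cholesterol synthesis, lipolysis and lipid handling, glucose use, futile cycles, endoplasmic reticulum stress, interferon response, circadian clock, proliferation, genes flanking Adcy3, and markers of white adipocytes, skeletal muscle, macrophages, lymphocytes, endothelium, fibroblasts and matrix, mural cells, nerve and Schwann cells, and erythroid cells. Lists with at least 5 tested members (24 of the 25) were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the lists. The rule for named genes was also fixed then. It takes Adcy3. It then takes, among called genes whose 3 libraries of a genotype all lie above the 3 of the other, with a mean CPM of at least 1 in a genotype and a symbol that is not a predicted or clone name, the 8 largest rises and the 8 largest falls. From each list it takes up to 3 called members with the smallest p, or the 2 with the smallest p where none was called. For marker lists and for the list with the smallest p it adds the member with the highest mean CPM. After the data were seen, 7 further lists were written: cytosolic chaperones, chaperonin subunits, glucocorticoid-inducible genes, fasting and FOXO genes, insulin-induced genes, collagen hydroxylases, and targets of growth hormone.

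Alternatives fixed beforehand were the size factors of DESeq2, upper-quartile factors or library size alone in edgeR, the Wald test of DESeq2 1.42.0, limma-voom, robust quasi-likelihood, no filter on low counts, a filter of CPM above 1 in 3 libraries, a threshold of 0.10, glmTreat against a 1.2-fold change, the replicate number as a block, per-library offsets for GC content and gene length (known for 99.9% of the genes tested), 1 surrogate variable from sva 3.50.0, and leaving out each library. For lists they were an estimated correlation, fry, camera on ranks, the CPM filter, the block, the DESeq2 factors and leaving out each library. A covariate for skeletal muscle RNA and the sum of Adcy3 with the row that has no symbol were added after the data were seen.

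The fit was tested on simulated counts for the same 14332 genes with 200 changed between the genotypes. It called 31.3% of the genes changed 1.5-fold, 70.1% of those changed 2-fold and 87.9% of those changed 4-fold, and 8.7% of its calls were genes that had not been changed. In a simulation of the list test on these genes, 4 of 200 lists without a change had a p under 0.05. Genes were drawn independently there, so it does not cover lists whose members move together. In the data the estimated correlation was 0.832 for skeletal muscle and 0.954 for erythroid markers. Reads and coverage along Adcy3 were not analysed here.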

Results

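Gene expression was measured by sequencing of polyadenylated RNA in brown adipose tissue, the fat that makes heat, from 20-week-old C57BL/6N mice. The study set wild type (3 libraries) against ADCY3∆AT (3 libraries), which lacks a truncated form of adenylyl cyclase 3 that the series title ties to cold and to the control of brown fat function. The comparison asks what the loss of this form does to gene expression in brown fat of mice on chow. Other differences that went with the genotype, such as in genetic background, collection or handling, cannot be told apart from this loss. Library totals were 15412766, 13758492 and 17489589 estimated counts in wild type and 18698546, 14799779 and 19592156 in the knockout. Mitochondrially encoded genes took 21.9% to 24.4% of the counts.

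Adcy3, which makes cyclic AMP from ATP, was at the same level in both genotypes within the spread between libraries, while a second row of the table without a gene symbol was near 0 in each knockout library. Adcy3 (ENSMUSG00000020654) lies on chromosome 12 from 4133103 to 4213525, on the plus strand of GRCm38. Its row held 208 ± 40.7 CPM in wild type and 201 ± 36.5 CPM in the knockout. The log2 fold change was -0.05 (SE 0.16, 95% interval -0.43 to 0.33, edgeR adjusted p = 0.894), and the exact permutation p was 0.8, two-sided, where 0.1 is the smallest this design allows. Its sign turned without WT replicate 1 (0.10) and without knockout replicate 1 (0.08). The second row, ENSMUSG66666620654 (the added row in what follows), ends in the same digits as the identifier of Adcy3, and the table gives no name, sequence or position for it. It held 215, 197 and 118 CPM in the wild-type libraries and 1.27, 0 and 0 CPM in the knockout libraries (edgeR adjusted p = 0.000845, exact permutation p = 0.1). The zeros allow up to 0.199 and 0.152 CPM. It took 45.5 ± 3.6% (SD, n = 3) of the sum of both rows in wild type and at most 0.75% in a knockout library. The sum, an addition made after the data were seen, was 384 ± 91.0 CPM (SD, n = 3) in wild type and 201 ± 35.9 CPM in the knockout, a log2 fold change of -0.93 (SE 0.19, edgeR adjusted p = 0.0339). That call ended without WT replicate 1 (-0.78), WT replicate 2 (-0.89), knockout replicate 1 (-0.81) or knockout replicate 2 (-0.91). Estimated counts can divide reads of shared exons between such rows, so the level of each row is less certain than their sum. Of the 9 tested genes that flank Adcy3, 0 were called by edgeR, by DESeq2 or by limma-voom, and 1 had an unadjusted p under 0.05 (Itsn2, log2 fold change 0.26, edgeR adjusted p = 0.144). The other with the smallest p was Dnmt3a (-0.17, adjusted p = 0.351).

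**Figure D1:**
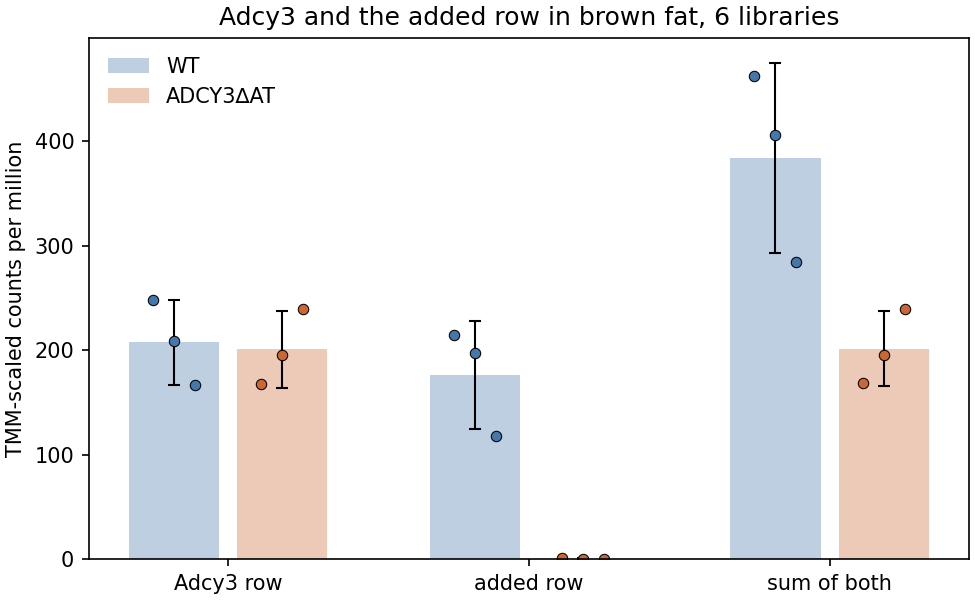
TMM-scaled CPM (vertical axis, from 0) of the Adcy3 row, the added row and their sum in wild type (blue) and ADCY3∆AT (orange). Bars are means of 3 libraries, error bars are SD and points are libraries (replicates 1 to 3 from left to right); the added row stands at 118 to 215 in wild type and at 0 to 1.27 in the knockout.

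Among the largest called changes, the knockout libraries held more RNA of 4 heat shock proteins, of the collagen prolyl hydroxylase P4ha1 and of the nuclear receptor Nr4a3. They held less RNA of 7 skeletal muscle genes, which may have been carried over with the wild-type tissue. The calls of Hspa1b, Hspa1a and the muscle genes ended in several fits without 1 library, as given below. In all, 616 of 14332 tested genes were called, 377 higher and 239 lower in the knockout, and 86 of the higher and 78 of the lower ones changed at least 2-fold. Of the 8 largest rises that the naming rule takes, 4 were chaperones that keep proteins folded. Hspa1b rose 22.7-fold (24.1 ± 11.8 CPM in wild type and 552 ± 445 CPM in the knockout), Hspa1a 17.9-fold, Hsph1 15.4-fold (19.4 ± 3.22 CPM in wild type and 299.6 ± 139 CPM in the knockout) and Hspb1 7.81-fold. P4ha1 rose 13.3-fold (10.3 ± 0.240 CPM in wild type and 138 ± 41.5 CPM in the knockout), and Thbs1, which encodes the matrix protein thrombospondin, rose by a log2 fold change of 3.46 (SE 0.29). Nr4a3 rose 9.26-fold (log2 3.21, SE 0.33) and Gfpt2, the entry enzyme of hexosamine synthesis, 5.62-fold (log2 2.49, SE 0.50). These 8 had edgeR adjusted p-values from 0.000490 (P4ha1) to 0.0344 (Gfpt2). Hspa1a and Hspa1b are near-identical copies, so how their reads were divided is uncertain. Of the 8 largest falls, 7 were skeletal muscle genes, given with their list below, and the other was Yy2, a zinc finger gene. Yy2 had 18, 31 and 18 counts in wild type and 0 in each knockout library, at least 8.68-fold lower against 3 counts per library (edgeR adjusted p = 0.0141).

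The split of calls depended on the scaling: 282 were higher and 274 lower with upper-quartile factors. Without WT replicate 1, 2 or 3 there were 162, 293 and 253 calls, and without knockout replicate 1, 2 or 3 there were 461, 223 and 304. These fits have 1 library fewer, so an ended call does not by itself show that it rested on that library. Among the 8 largest rises and Yy2, the calls that ended in such fits were those of Hspa1b (without any 1 WT library, or knockout replicate 2), Hspa1a (any but knockout replicate 1), Gfpt2 (any 1 WT library) and Yy2 (WT replicate 1). The log2 fold changes ran from 3.81 to 5.02 for Hspa1b, 3.40 to 4.72 for Hspa1a and 1.76 to 2.79 for Gfpt2. Their direction could not turn, since the naming rule takes only genes whose libraries do not overlap between genotypes. All 616 called genes had libraries that did not overlap between genotypes, as did 29% of all tested genes, against 10% by chance.

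**Figure D2:**
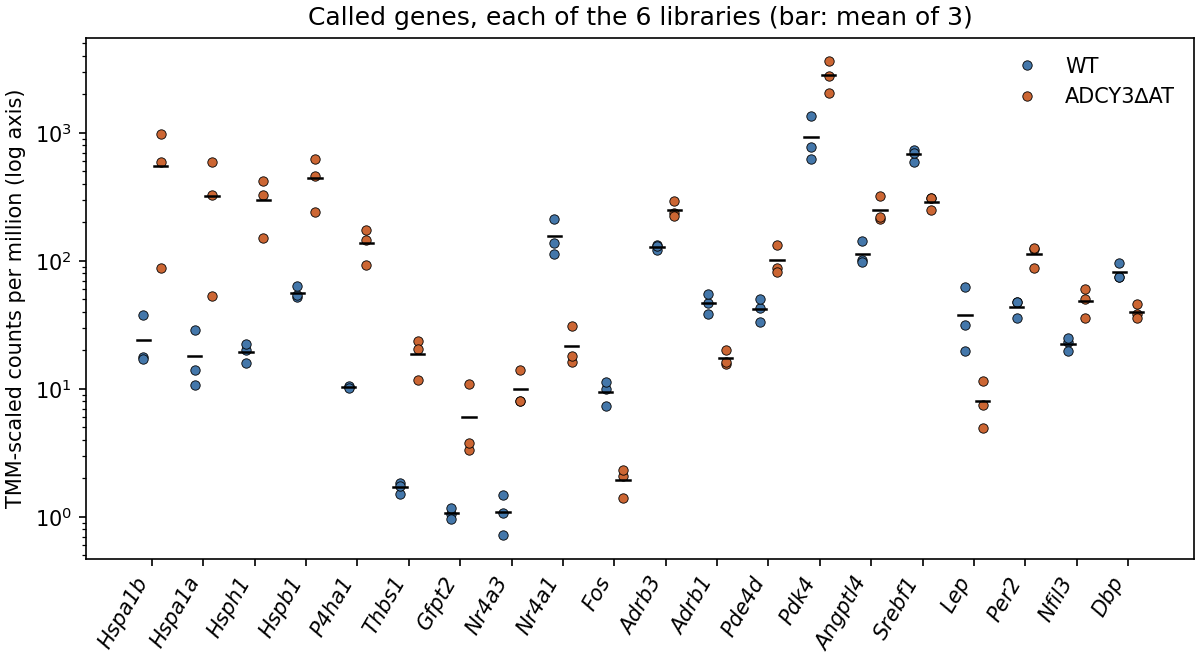
TMM-scaled CPM (vertical log axis) of 20 called genes in each library of wild type (blue) and ADCY3∆AT (orange), with the mean of 3 as a bar. Hspa1b spans 88.6 to 975.9 CPM within the knockout, more than P4ha1 (92.4 to 174.1 CPM).

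The list of immediate targets of cyclic AMP holds immediate early and CREB-responsive genes, and its members moved both ways. Cyclic AMP itself was not measured, so these changes do not show its level. Of 32 tested, 4 rose, 5 fell and 23 were not called (14 were called when adjusted over the list alone, 6 higher and 8 lower). Nr4a1 fell (155 ± 51.7 CPM in wild type and 21.8 ± 7.91 CPM in the knockout, 7.09-fold lower) while its relative Nr4a3 rose 9.26-fold. Fos, an early response gene, fell (9.50 ± 1.95 CPM in wild type and 1.94 ± 0.485 CPM in the knockout, 4.84-fold lower). The 3 genes had the same edgeR adjusted p (0.00378), and each call was kept in all 6 fits without 1 library. The list as a whole was not called by camera (adjusted p = 0.757), and 1 rise and 5 falls were left without WT replicate 1 and likewise without WT replicate 3. Without knockout replicate 1 there were 2 rises and 8 falls.

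Receptors and enzymes of the cyclic AMP pathway also moved apart. Of 37 tested members, 2 rose, 1 fell and 34 were not called (4 higher and 1 lower when adjusted over the list alone). Adrb3, the main beta-adrenergic receptor of rodent adipocytes, rose 1.94-fold (129 ± 6.01 CPM in wild type and 251 ± 36.8 CPM in the knockout), and Pde4d, which breaks down cyclic AMP, rose 2.40-fold (log2 1.26, SE 0.21). Adrb1, another beta-adrenergic receptor, fell (46.7 ± 7.96 CPM in wild type and 17.3 ± 2.36 CPM in the knockout, 2.70-fold lower). Adjusted p-values in edgeR were 0.00353 for Adrb1, 0.00435 for Adrb3 and 0.0192 for Pde4d, whose call ended without WT replicate 1 or WT replicate 3. The log2 fold change of Pde4d ran from 1.02 (without knockout replicate 1) to 1.42 (without WT replicate 2). Camera placed the list higher in the knockout (adjusted p = 0.037), with adjusted p = 0.866 with an estimated correlation and 0.303 without WT replicate 3.

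Among 27 thermogenic genes of brown fat, 1 rose (Adrb3, which is on both lists) and 26 were not called (2 higher when adjusted over the list alone). Ucp1, the uncoupling protein that lets mitochondria make heat, held 4786 ± 963 CPM in wild type and 4239 ± 231 CPM in the knockout (log2 fold change -0.18, 95% interval -0.49 to 0.14, edgeR adjusted p = 0.5). Cidea held 1835 ± 68.7 CPM in wild type and 1893 ± 104 CPM in the knockout, and the log2 fold change of Ppargc1a, a coactivator of mitochondrial genes, was 1.01 (edgeR adjusted p = 0.0609); Ucp1, Cidea and Ppargc1a were picked after their values were seen. Camera did not call the list (adjusted p = 0.127).

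None of 76 nuclear genes of oxidative phosphorylation was called by edgeR, DESeq2 or limma-voom, 11 had an unadjusted p under 0.05, and 73 had a negative log2 fold change (median -0.10). Uqcrq held 837 ± 30.2 CPM in wild type and 727 ± 17.2 CPM in the knockout (log2 -0.20, edgeR adjusted p = 0.107) and Ndufb11 357 ± 8.41 CPM in wild type and 314 ± 11.9 CPM in the knockout (log2 -0.18, adjusted p = 0.128). Atp5b, the member with the highest level, had a log2 fold change of 0.02 (adjusted p = 0.903), which was -0.02 with upper-quartile factors and -0.01 without WT replicate 3. Camera called the list lower (adjusted p = 1.35e-07), with adjusted p = 0.866 with an estimated correlation, so a shift of the group is not settled. Of the 13 mitochondrially encoded genes 0 were called by edgeR, DESeq2 or limma-voom and 1 had an unadjusted p under 0.05. These included mt-Nd6 (log2 -0.20, edgeR adjusted p = 0.219) and mt-Nd3 (-0.46, adjusted p = 0.241), and camera gave adjusted p = 0.135.

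Single genes of lipid and cholesterol synthesis fell. Srebf1, which drives the transcription of fatty acid synthesis genes, fell (678 ± 73.1 CPM in wild type and 290.3 ± 36.6 CPM in the knockout, 2.34-fold lower, edgeR adjusted p = 0.00235) and kept its call in all 6 fits without 1 library. In the lipogenesis list of 23 genes, 2 fell (also 2 when adjusted over the list alone), the other being Dgat1 (1.27-fold lower, edgeR adjusted p = 0.0391), which makes triglycerides and lost its call without any 1 library (log2 from -0.38 to -0.29). Fasn, named after its value was seen, held 24737 ± 3437 CPM in wild type and 24635 ± 5709.6 CPM in the knockout. In cholesterol synthesis 2 of 22 fell (5 when adjusted over the list alone). Msmo1 was 1.85-fold lower (edgeR adjusted p = 0.0101) and Mvd 1.82-fold lower (adjusted p = 0.0444), the latter not called without WT replicate 1, WT replicate 3, knockout replicate 2 or knockout replicate 3 (log2 from -1.02 to -0.71). Camera called cholesterol synthesis lower (adjusted p = 0.015), with adjusted p = 0.866 with an estimated correlation and 0.747 without knockout replicate 3. It did not call lipogenesis (adjusted p = 0.135). Without WT replicate 2, edgeR called 1 rise and 1 fall in lipogenesis. Without knockout replicate 3 it called 1 rise and 1 fall in cholesterol synthesis.

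Single genes of fuel use rose. Pdk4, which holds back glucose oxidation, rose 3.06-fold (923 ± 391 CPM in wild type and 2825 ± 784 CPM in the knockout), the 1 call among 27 fatty acid oxidation genes (1 when adjusted over the list alone). Angptl4, an inhibitor of lipoprotein lipase, rose 2.21-fold, the 1 call among 21 lipolysis and lipid handling genes (1 when adjusted over the list alone). Slc6a8, the creatine transporter, rose 1.36-fold, the 1 call among 9 genes of futile cycles (1 when adjusted over the list alone). Their edgeR adjusted p-values were 0.0275 for Pdk4, 0.0194 for Angptl4 and 0.0452 for Slc6a8. Of 28 genes of glucose use 0 were called by edgeR, 3 by DESeq2 and 0 by limma-voom, and 8 had an unadjusted p under 0.05. When adjusted over the list alone 7 were called, 1 higher and 6 lower. Pfkl had a log2 fold change of 0.33 (edgeR adjusted p = 0.0706) and Slc2a4 of -0.30 (adjusted p = 0.0723). Camera gave adjusted p = 0.317 for fatty acid oxidation, 0.647 for lipolysis, 0.647 for futile cycles and 0.144 for glucose use. Without 1 library, the calls of Pdk4 and Angptl4 ended without WT replicate 1 or 3 (Pdk4 also without knockout replicate 2), and that of Slc6a8 was kept only without WT replicate 2, with log2 values from 1.39 to 2.01 for Pdk4, 0.94 to 1.34 for Angptl4 and 0.38 to 0.55 for Slc6a8.

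Clock genes changed in both directions, with 3 of 18 higher and 2 lower (4 higher and 3 lower when adjusted over the list alone). Per2 rose 2.57-fold (43.7 ± 6.75 CPM in wild type and 112 ± 20.6 CPM in the knockout) and Nfil3 2.16-fold (log2 1.11, SE 0.18), while Dbp fell (81.9 ± 12.3 CPM in wild type and 40.0 ± 5.43 CPM in the knockout, 2.05-fold lower). Their edgeR adjusted p-values were 0.00547, 0.0174 and 0.00685, and the Nfil3 call ended without WT replicate 1, WT replicate 2 or knockout replicate 3 (log2 from 0.94 to 1.29). The list had 2 calls without WT replicate 2 and 2 without knockout replicate 3, and 3 without WT replicate 1 or 3. Camera gave adjusted p = 0.647. The sources used here do not give the time of collection, so it cannot be told apart from the genotype for these genes.

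Of 28 genes of endoplasmic reticulum stress, 2 rose and 26 were not called (5 higher when adjusted over the list alone). Hsp90b1, a chaperone of that compartment, rose 1.24-fold (142 ± 3.66 CPM in wild type and 176 ± 5.85 CPM in the knockout, edgeR adjusted p = 0.0331), and Nfe2l1, a transcription factor held in its membrane, rose 1.22-fold (adjusted p = 0.0469). Both calls ended with upper-quartile factors. That of Nfe2l1 ended without any 1 library (log2 from 0.25 to 0.30) and that of Hsp90b1 without any but knockout replicate 1 (0.29 to 0.34). Camera called the list higher (adjusted p = 0.0345), with adjusted p = 0.866 with an estimated correlation, 0.0748 without WT replicate 1 and 0.0505 without knockout replicate 2. Of 23 interferon response genes, 1 rose and 1 fell (2 called when adjusted over the list alone), and camera gave adjusted p = 0.647. Bst2 rose 1.52-fold (edgeR adjusted p = 0.0423) and, of the fits without 1 library, was called only without WT replicate 3 (log2 from 0.52 to 0.76). The list had at most 1 call in any such fit. Of 10 proliferation genes 0 were called by edgeR or limma-voom and 0 of the 5 with an adjusted p in DESeq2, and 1 had an unadjusted p under 0.05 (Aurka, log2 -0.88, edgeR adjusted p = 0.139, beside Mcm2 with -0.29 and adjusted p = 0.430). Camera gave adjusted p = 0.757.

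Several transcripts of skeletal muscle, such as Myh4 and Atp2a1, were near 0 in the 3 knockout libraries and differed widely among the wild-type ones. Of 17 tested markers, 8 fell and 9 were not called (14 lower when adjusted over the list alone). Myh4, a fast myosin heavy chain, held 7.05, 27.2 and 164.8 CPM in WT replicates 1, 2 and 3 and at most 0.22 CPM in the knockout, and Atp2a1, a calcium pump, held 4.31, 26.8 and 156.4 CPM and at most 0.33 CPM. The naming rule also took Tnnt3, Tnni2, Ckm, Acta1 and Actn3, which had wild-type means of 21.1, 9.93, 31.1, 45.8 and 11.5 CPM. These 7 genes had edgeR adjusted p-values from 0.0271 (Myh4) to 0.0473 (Ckm). Myl1, the marker with the highest mean level over all libraries, held 53.5 ± 13.8 CPM in wild type and 45.3 ± 1.91 CPM in the knockout (adjusted p = 0.410). Camera called the list lower (adjusted p = 0.000629), with adjusted p = 0.866 with an estimated correlation. The number of markers called was 15 without WT replicate 1, 1 without WT replicate 2, 5 without WT replicate 3 and 0 without any 1 knockout library, and limma-voom called 0 of the 17. In the fits without 1 library the log2 fold changes ran from -9.47 to -6.93 for Myh4 and -7.60 to -4.76 for Acta1. The direction of the 7 named genes that fell could not turn there, since the naming rule takes only genes whose libraries do not overlap. Of the 608 calls outside this list, 226 were also called without WT replicate 3; as the libraries of called genes do not overlap between genotypes, the direction of none could turn.

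Among 12 white adipocyte markers, 1 fell and 11 were not called (1 higher and 3 lower when adjusted over the list alone). Lep, the hormone leptin, fell (37.9 ± 22.1 CPM in wild type and 7.97 ± 3.26 CPM in the knockout, 4.72-fold lower, edgeR adjusted p = 0.0312), a call that ended without WT replicate 1 or 3 or knockout replicate 1 or 2 (log2 from -2.60 to -1.67). Car3, the marker with the highest level, held 3849 ± 382 CPM in wild type and 3256 ± 230.0 CPM in the knockout (adjusted p = 0.172). Camera called the list lower (adjusted p = 0.0237), with adjusted p = 0.866 with an estimated correlation, 0.0889 without WT replicate 3 and 0.203 without knockout replicate 3.

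Markers of other cell types gave few calls. Cspg4, a marker of pericytes, fell (103 ± 7.19 CPM in wild type and 70.1 ± 2.96 CPM in the knockout, edgeR adjusted p = 0.00933), the 1 call among 12 mural cell markers (1 higher and 2 lower when adjusted over the list alone). Rgs5, the highest of them, had a log2 fold change of 0.32 (adjusted p = 0.102). Ighm, an immunoglobulin heavy chain and the highest of 4 tested lymphocyte markers, was the 1 call among them (7.28 ± 1.15 CPM in wild type and 3.09 ± 0.527 CPM in the knockout, adjusted p = 0.0154, 1 when adjusted over the list alone), and it was not called without WT replicate 1 or 3 (log2 from -1.35 to -1.10). Of 15 endothelial markers 0 were called by edgeR, 2 by DESeq2 and 0 by limma-voom, 9 had an unadjusted p under 0.05 and 1 was called when adjusted over the list alone. Egfl7 (log2 -0.27, adjusted p = 0.0540) and Emcn (-0.33, 0.118) had the smallest p, and Cdh5 the highest level (185 ± 9.61 CPM in wild type and 179 ± 5.30 CPM in the knockout). Of 22 fibroblast and matrix genes 0 were called by edgeR, 1 by DESeq2 and 0 by limma-voom, and 4 had an unadjusted p under 0.05. Postn had a log2 fold change of 0.31 (adjusted p = 0.0858), Fn1 of 0.43 (0.121) and Sparc, the highest, of 0.14 (0.284).

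No call was made by edgeR or limma-voom among 14 macrophage, 8 nerve and Schwann cell or 6 erythroid markers, or by DESeq2 among the 13, 8 and 5 of them to which it gave an adjusted p. In edgeR, 0, 3 and 0 of these genes had an unadjusted p under 0.05. Itgam (log2 0.45), Cd14 (-0.41) and Cd74, the highest macrophage marker (-0.07), had edgeR adjusted p-values of 0.379, 0.379 and 0.904. Mbp, the highest nerve marker, had a log2 fold change of 0.51 (adjusted p = 0.159). Without knockout replicate 3, 3 nerve markers were called. The erythroid genes Slc4a1 (-0.97), Hba-a1 (-0.38) and Hbb-bs, the highest (-0.18), had adjusted p-values of 0.336, 0.435 and 0.772. The log2 fold change of Cd74 turned sign without WT replicate 3 (0.15) or knockout replicate 1 (0.18), and that of Hbb-bs likewise (0.11 and 0.05). Camera gave adjusted p-values of 0.647 for macrophages, 0.757 for mural cells, 0.867 for endothelium, 0.268 for fibroblasts and matrix, 0.212 for nerve, 0.226 for erythroid cells and 0.757 for the genes flanking Adcy3.

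Across lists, camera with its preset correlation called 6 of 24, with 2 higher and 4 lower in the knockout, and 0 with an estimated correlation, where 0 lists had an unadjusted p under 0.05. Without knockout replicate 1 there were 11. Other divisions of the same 6 libraries into 3 and 3 gave 6 to 12 lists.

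**Figure D3:**
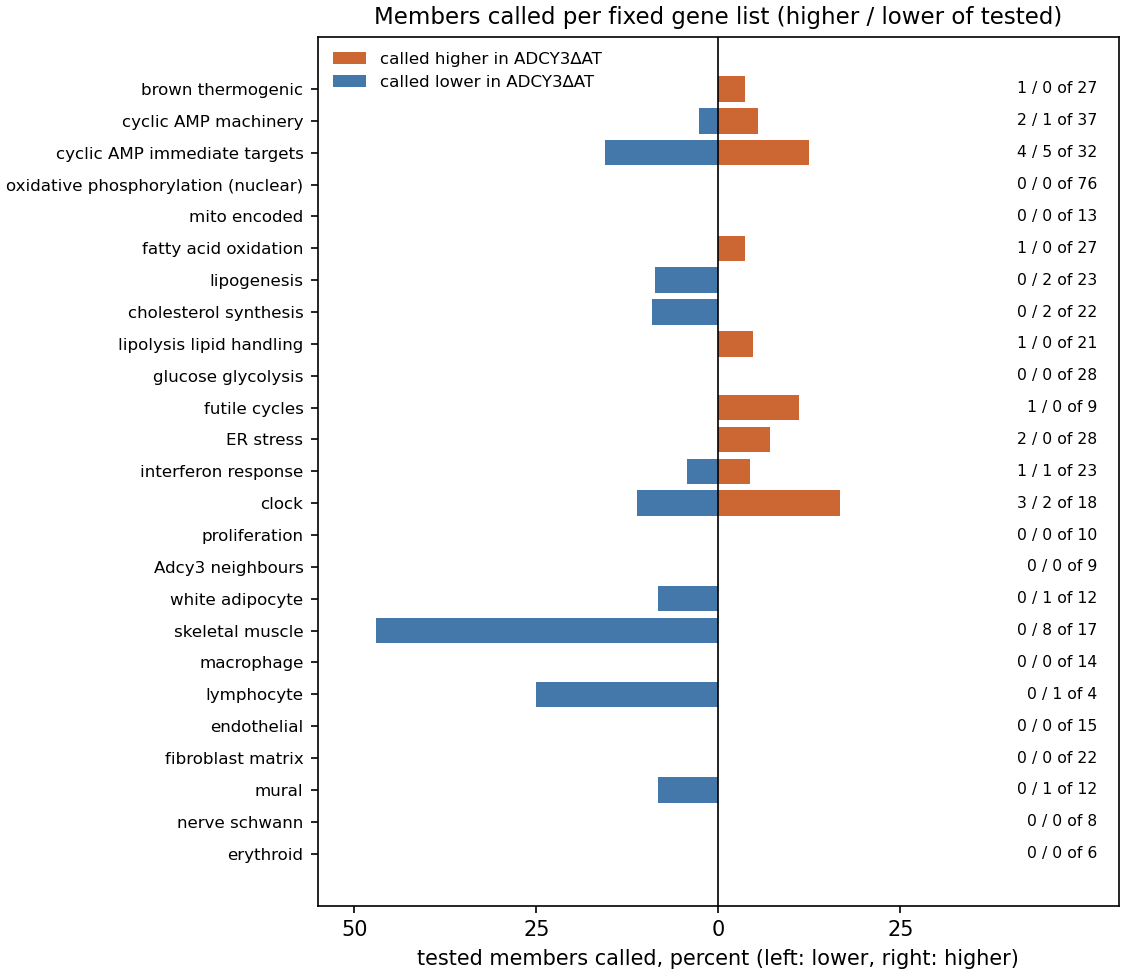
Percent (horizontal axis) of the tested members of each fixed list (vertical axis) that edgeR called higher (orange, to the right) or lower (blue, to the left) in ADCY3∆AT; the text at the right gives the counts called higher and lower of those tested. Skeletal muscle has 8 of 17 called lower, immediate targets of cyclic AMP 4 higher and 5 lower of 32.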

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

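Of the alternatives below, the skeletal muscle covariate and the sum of Adcy3 with the added row were chosen after the data were seen. The number of called genes (616) stayed within 1.5 times under other scalings, limma-voom, robust quasi-likelihood, the stricter CPM filter, the GC and length offsets and the surrogate variable. It was 943 with the Wald test of DESeq2 (575 shared with the 616), 1951 with no filter on low counts, 1375 at a threshold of 0.10, 160 with glmTreat against 1.2-fold, and 162 to 461 without 1 library. The thresholds act by construction; for DESeq2 and the missing filter the cause was not tested. With the replicate block there were 324 calls. The labels do not say whether a shared number marks a pair. Same-numbered libraries deviated from their genotype means with correlations of 0.001, -0.007 and -0.049, and no library correlated best with its own number. With 3 libraries per genotype, these correlations cannot exclude a shared litter, day or batch. With the muscle covariate 3 genes were called, 2 of them among the 616. Folds were kept for some genes (log2 3.95 for Hsph1, 3.55 for P4ha1, 3.45 for Thbs1) and smaller for others (-1.13 for Lep, 0.88 for Per2). Genotype takes 75.5% of the variance of that score, so the score and the genotype are largely confounded.

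The log2 fold change of Adcy3 ran from -0.20 to 0.10 without 1 library and was -0.68 with the muscle covariate (unadjusted p = 0.0193, adjusted p = 0.562), and its sum with the added row gave -0.93. Its adjusted p lay between 0.539 and 0.962 over 16 alternatives. The added row was called lower in each of 20. The count of lists (6) was 0 with an estimated correlation, 0 with fry and 5 to 11 without 1 library. With the muscle covariate the cyclic AMP machinery list turned lower (adjusted p = 0.602), and the log2 fold changes of genes that had not been called turned for Atp5b (-0.0651), Myl1 (0.47), Cd14 (0.46), Cd74 (0.51), Rgs5 (-0.0189), Hba-a1 (0.0461) and Hbb-bs (0.26). That of Atp5b was -0.0203 with upper-quartile factors. Without 1 library, Atp5b ran from -0.0088 to 0.0419, Cd74 from -0.35 to 0.18 and Hbb-bs from -0.42 to 0.11. The cause of these turns was not tested. In the simulation 31.3% of 1.5-fold changes were recovered.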

Other observations

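All gene lists and tests in this part were chosen after the results were seen, except the count over divisions of the libraries. Part of the genes that glucocorticoids induce and of those raised in fasting rose in the knockout, while part of those that insulin induces fell. Of 19 tested glucocorticoid-inducible genes 9 rose and 1 fell, with Tsc22d3 2.36-fold higher (log2 1.24, SE 0.17) and Cdkn1a 2.53-fold higher (edgeR adjusted p = 0.00933 and 0.00539). The calls of Tsc22d3 and Cdkn1a were kept in all 6 fits without 1 library. Those of Fkbp5, Zbtb16, Ddit4 and Errfi1, which also rose, were kept in 1, 2, 2 and 2 of the 6. Dusp1, the 1 that fell, is also an early response gene. Of 18 genes of fasting and FOXO signalling 7 rose, among them Ccng2 (33.8 ± 5.51 CPM in wild type and 93.3 ± 2.74 CPM in the knockout, 2.77-fold), Pik3ip1 (4.62-fold) and Trp53inp1 (4.52-fold). The calls of Ccng2, Pik3ip1, Trp53inp1 and Gabarapl1 were kept in all 6 such fits, and those of Foxo3 and Depp1 in 4 and 3. Of 14 insulin-induced genes 4 fell: Srebf1 and Lep, given in the report, Hcar1 (48.1 ± 19.0 CPM in wild type and 18.7 ± 2.55 CPM in the knockout, edgeR adjusted p = 0.0275) and Angptl8. Fasn and Scd1 of that list were not called. Pdk4 stands on both lists of genes that rose, and Pdk4, Per2 and Angptl4 are on fixed lists as well. Without 1 library the calls ran from 4 to 9, 4 to 7 and 1 to 4 in these lists, lowest without WT replicate 1 (4 and 1 in the first and last) and WT replicate 3 (4 in the fasting list), and 1 in the insulin list without knockout replicate 1 too. The Hcar1 call ended without WT replicate 1 or any 1 knockout library (log2 from -1.57 to -1), and that of Angptl8 was kept only without WT replicate 2 (-1.67 to -1.03). Camera with its preset correlation called all 3 lists. As the lists were written after these results were seen, those calls cannot count as support. With an estimated correlation the adjusted p of camera was 0.118, 0.115 and 0.115. When and how the tissue was collected is not given in the sources used here. A difference in collection or in the state of the animals therefore cannot be told apart from the genotype for these genes.

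Of 10 tested collagen hydroxylases 4 rose and 6 were not called (adjusted p = 0.115 with an estimated correlation): P4ha1, P4ha2 (4.08-fold, 6.45 ± 0.661 CPM in wild type and 26.4 ± 5.41 CPM in the knockout), Plod2 (3.58-fold) and Plod1, whose call ended without WT replicate 1 or 2 or knockout replicate 2 or 3 (log2 from 0.38 to 0.52). Of 9 targets of growth hormone and STAT5 only Cish was called, at 120.3 ± 28.4 CPM in wild type and 11.6 ± 7.81 CPM in the knockout (10.3-fold lower, edgeR adjusted p = 0.00614). Its log2 fold change of -3.37 was -4.03 without knockout replicate 1 and -3.04 without knockout replicate 2. Its neighbours on chromosome 9, Mapkapk3 (1.60-fold) and 6430571L13Rik (8.02-fold), were lower too. Of 47 tested genes that start within 1 Mb of Cish 7 were called, 5 of them lower, against 4.3% of all tested genes called. The 7 include Cish and these neighbours, and the window was chosen after the fall of Cish was seen. Some genes differed with little spread inside a genotype. Entpd4 held 458 ± 30.7 CPM in wild type and 176 ± 23.3 CPM in the knockout and Wdfy1 9.97 ± 0.582 CPM in wild type and 34.6 ± 1.87 CPM in the knockout (edgeR adjusted p = 0.00112 and 0.000316). Gm5512 had 138, 141 and 181 counts in wild type and 0 in each knockout library, at least 57.4-fold lower against 3 counts per library. Gm16867, which overlaps Entpd4 on chromosome 14, held 8.82 ± 0.905 CPM in wild type and 0.0844 ± 0.146 CPM in the knockout. Wdfy1 lies on chromosome 1 and Gm5512 on chromosome 19, while Adcy3 lies on chromosome 12. Whether the knockout causes these differences was not tested. Other genetic differences that went with the genotype cannot be told apart from it here, for these or any other called genes.

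The division of the libraries by genotype called 616 genes, and the highest count among the other divisions into 3 and 3 was 2 (1 of 10 reached 616). For gene lists the real count was 6 and the highest other 12, and 10 of 10 divisions reached 6. With 10 divisions a share under 0.05 cannot be had in either case. The preset correlation thus gave as many or more lists when genotypes were mixed, so the 6 lists carry little weight of their own.

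Cytosolic chaperones were higher in the knockout in 21 of 28 tested members, with 9 called without WT replicate 1, 10 without WT replicate 2, 14 without WT replicate 3 and 11 without knockout replicate 2. Of 8 subunits of the chaperonin complex 7 rose as well (3 with upper-quartile factors, 1 without WT replicate 1, and 2 without WT replicate 2, knockout replicate 2 or knockout replicate 3). With an estimated correlation the adjusted p was 0.115 for each list.

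Reads shared between Hspa1a and Hspa1b cannot account for the higher cytosolic chaperones, since 19 of the 26 members outside this pair were called higher. Scaling does not account for them either, since at least 18 of 28 were called higher under each of 3 other scalings. For the chaperonin subunits the median log2 fold change was 0.416 with TMM and 0.377 with upper-quartile factors (median SE 0.079 and 0.083). The median log2 fold change of all tested genes was -0.007 with TMM and -0.045 with upper-quartile factors. This shift is small beside the subunits' median, which argues against scaling as the cause of their rise as a set. Scaling is not excluded for each of the 8, since the lowest 95% interval reached -0.036, that of a subunit which TMM did not call either. How animals or tissue were handled may have gone with the genotype (the mean log2 CPM of the 28 members differed by 0.832 between knockout libraries and by 0.295 between wild-type ones), so handling and genotype cannot be told apart in this design, and an effect of genotype remains open and untested.

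Skeletal muscle transcripts in wild type may come from muscle carried over with the tissue. Of 17 tested muscle genes 16 (all but Tnnc1) had their highest wild-type value in replicate 3 and their lowest in replicate 1, which is consistent with a single varying source. Among the 16, Myh4, Atp2a1 and Acta1 held 164.8, 156.4 and 117.5 CPM in WT replicate 3. Myl1 and Tnnc1 had knockout means close to those of wild type and were not called. Why the knockout libraries have so little was not tested, and a genotype effect on the tissue remains open.

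The added row may be the truncated transcript that the knockout removes. It took at most 0.75% of the sum of both rows in a knockout library and 41.5% to 48.5% in the wild-type libraries. The table gives no sequence or position for it, which leaves its identity open. If reads moved to Adcy3 by the estimation of counts were the whole cause of its loss, the sum of both rows would not change. The log2 fold change of the sum was -0.93 (95% interval -1.36 to -0.51), which argues against this. That sum was chosen after the data were seen, and its exact permutation p was 0.1. It ran from -1.11 to -0.78 without 1 library, and its call ended in some of these fits, as given above.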
